A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

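Messenger RNA levels were measured by RNA sequencing in Saccharomyces cerevisiae of the CEN.PK122-alpha background grown in a chemostat on limiting glucose, where the culture passes through the yeast metabolic cycle. Per the labels' protocols, 5 time points of 3 consecutive cycles were sampled in a wild-type strain (WT) and in a strain carrying the W89A substitution in Yaf9 (W89A), which gives 30 libraries in 10 groups of 3. Each strain's 3 libraries of a time point came from consecutive cycles and no separate cultures were stated. The p-values therefore measure spread between cycles, and the strain is confounded with its culture.

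The deposited count table holds whole-number counts of reads per gene, which the authors made before deposit. It has 7127 features, of which 333 had no count in any library and 6047 had an identifier that matched a locus tag of the yeast R64 reference. Library totals ranged from 16540627 to 20260295 counts. The authors' comparison tables also hold, as deposited, a signal per library, which is the count divided by a size factor per library, and FPKM values, which are per gene length and library total. The signal and FPKM values were not used. The aligner, the counting tool and the annotation were not given in the sources used here. The only genome build in the submitters' processing notes is mm9, a mouse assembly, although the identifiers are those of yeast genes. Start and end of 5912 of 5921 genes with coordinates in both sources equalled those of the yeast R64 reference, and coordinates are given on R64. The authors also deposited a comparison table for each time point, with log2 fold changes and p-values by the authors. These tables were used to set counts of calls side by side, to take gene symbols and to read which library stood at which time point. Strand was not stated, so reads of overlapping and antisense genes, like those of near-identical copies such as THI5, THI11, THI12 and THI13, the PAU genes and Ty elements, were treated as uncertain between members.

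Time points were taken from the number order of the library titles. In the authors' comparison tables, the first-cycle W89A library that this order puts at time point 4 stood at time point 5, and the one it puts at time point 5 stood at time point 4. The counts of all other libraries stood at the same time point in both. Values are given by the title order. Values with these 2 libraries exchanged, or left out, are given beside many, but not all, values of time points 4 and 5 and beside counts that moved by more than 1.5 times.

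All 30 libraries entered a single edgeR 4.0.16 fit (R 4.3.3) with TMM normalization, filterByExpr, robust quasi-likelihood dispersions and a mean per group; 6256 genes were kept and 871 removed. The common biological coefficient of variation was 0.1995 by the title order, 0.1639 with the libraries exchanged and 0.1636 with both left out. W89A was compared with WT at each time point and as an average over the 5 time points. An F test of 4 contrasts asked whether the strain difference changed between time points (the interaction), and the same kind of test within each strain asked which genes changed over the cycle. Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05; a stricter count asked in addition for an absolute log2 fold change of at least 1. Values per library are CPM, counts scaled to the normalized library size. Their log2 used a prior count of 2. Fold changes carry their standard error (SE) and means per group their standard deviation (SD).

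Gene lists of processes, complexes and gene families were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01 between genes, over 40 lists with at least 5 tested members and 6 contrasts, with Benjamini-Hochberg adjustment over all 240 pairs. Of the 104 pairs past the threshold, 0 stayed past it with an estimated correlation. Genes of a cycling list move together between libraries, but whether this alone caused the loss was not tested. The fry test, which asks whether a list's genes move one way without comparing them with other genes, passed for 72 of the 240 pairs, 59 of them shared with camera. Camera calls below therefore describe a list relative to other genes in these libraries. Counts of list members with the first-cycle libraries exchanged or left out were always adjusted over all genes, never over the list alone.

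Genes are named by this rule: Yaf9, Swr1, Htz1 and the other subunits of the SWR1 and NuA4 complexes; per time point, the 5 genes with the highest and the 5 with the lowest fold change among those past the threshold, without overlap between the 3 and 3 libraries, with a mean of at least 10 CPM and a symbol; 10 and 10 for the average, with the same sign at all 5 time points; the 10 smallest p of the interaction; for the WT cycle the 4 genes of largest range per time point of the peak; and up to 2 members in each direction of each list described. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Alternatives concerning the exchanged libraries, and list tests without each library of time point 1, were added after seeing the data.

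Amplitude was the median over cycling genes (5229 past the threshold in a test of time over both strains) of the log2 range over the 5 time points of a cycle, compared between 3 and 3 cycles by an exact permutation test. Group means of log2 CPM, centred on each strain's mean over the cycle, were correlated across those genes, and each library was placed at its nearest position on the line joining the WT time points in order. Replicate numbers within a strain mark shared cycles, per the labels' protocols. The estimated correlation between libraries of a cycle was 0.00184, by title order alone. In that order, deviations from group means at W89A time points 4 and 5 correlated at -0.64, -0.426 and -0.073 in cycles 1 to 3. The low estimate therefore does not show that libraries of a cycle are independent. Alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, leaving out the 10 most abundant genes and the mitochondrial genome, a replicate block, fits of fewer libraries, and leaving out each library or cycle in turn. DESeq2 called more unchanged simulated genes than edgeR (9.2% of its calls for 1 time point and 19.3% for the interaction, against 3.3% and 1%).

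The procedures were tested on simulated counts with known changes. For the shares recovered, 66 or 67 genes per fold were changed, all drawn from genes with a mean of at least 10 CPM. Recovery of genes with lower counts was not measured. For 1 time point, the edgeR test recovered 41.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 98.5% of those changed 4-fold among 6221 genes tested. For the interaction the shares were 6%, 47.8% and 93.9% of 6221 genes, for the average 89.6%, 98.5% and 100% of 6219, and for the cycle in a single strain 46.3%, 76.1% and 98.5% of 6212. Camera found the changed list and 0 of 38 unchanged lists, but simulated genes varied independently, so this cannot judge the preset correlation between genes. A position of 2.5, simulated on the line joining the WT time points itself, was found at 2.5, so libraries off that line were not tested. A W89A amplitude of 0.7 of that of WT, simulated at all time points except 3, was found as 0.762 over 3000 genes. Time point 3 was set midway between WT time points 2 and 3 without that scaling. The gap therefore does not show whether the amplitude measure understates a loss.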

Results

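RNA was sequenced from 30 libraries of the budding yeast CEN.PK122-alpha, 15 of a wild-type strain (WT) and 15 of a strain with the W89A substitution in Yaf9, a subunit shared by the SWR1 histone exchange complex and the NuA4 histone acetyltransferase. In each strain, 5 time points of the metabolic cycle were sampled in 3 consecutive cycles, so each of the 10 groups held 3 libraries. Each library held 16540627 to 20260295 counts. The first-cycle W89A libraries of time points 4 and 5 stand exchanged in the authors' own comparison tables, and values for that assignment are given beside many of the results.

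In WT, genes for making ribosomes were at their highest at time point 2, genes of respiration and of the mitochondrial ribosome followed at time points 3 and 4, and stress and proteasome genes came last, at time point 5. Of 135 ribosome biogenesis genes, 133 peaked at time point 2, as did 133 of 138 cytosolic ribosomal protein genes. The respiratory chain and ATP synthase peaked at time point 3 for 32 of 39 genes, and the mitochondrial ribosome at time point 4 for 69 of 74. All 37 proteasome genes and 36 of 45 heat shock and stress genes peaked at time point 5. All 135 ribosome biogenesis, 136 cytosolic ribosome, 73 mitochondrial ribosome, 39 respiratory chain, 37 proteasome and 44 heat shock genes changed over the WT cycle, the same numbers when adjusted over the list alone.

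Among single genes with the largest ranges of fitted log2 values over the WT cycle, AQR1, a plasma membrane exporter, peaked at time point 1 with a range of 5.85, beside BSC1 (5.32), PRM7 (4.32) and the tRNA methyltransferase subunit gene TRM11 (4.22). The RNA helicase gene DBP2 peaked at time point 2 (6.12), with NSR1 (5.66), GFD2 (5.44) and the glucose transporter gene HXT4 (5.31). Time point 3 held the peaks of the allantoate permease gene DAL5 (4.08), the citrate synthase genes CIT2 (3.98) and CIT1 (3.44), and ACH1 (3.80). Time point 4 held those of the acetate transporter gene ADY2 (7.09), PXA2 (5.36), CAT2 (5.22) and the glycerol importer gene STL1 (5.04). At time point 5 peaked SPG1 (6.65), the catalase gene CTT1 (6.56), the acetyl-CoA synthetase gene ACS1 (6.22) and the alcohol dehydrogenase gene ADH2 (6.12). These 20 genes kept their calls without any single cycle. In all, 4977 of 6256 genes changed over the cycle in WT (edgeR, Benjamini-Hochberg), 2920 of them with a range of at least 1 on the log2 scale.

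In W89A the same test passed for 4155 genes, 2214 of them with a range of at least 1, and for 4725 genes with the first-cycle libraries exchanged. Ribosome biogenesis cycled in W89A in all 135 genes and cytosolic ribosomal protein genes in 132 of 138. The histones cycled in 4 of 11 genes, against 10 in WT, and in 4 with the libraries exchanged and 3 with both left out. By title order the mitochondrial ribosome cycled in 56 of 74 genes and mitochondrial import and assembly in 20 of 37, against 73 and 37 in WT, but exchanged in 72 and 33 and with both left out in 71 and 32, so most of this loss rested on the assignment of the 2 libraries. By title order, calls were shared by 3905 genes. In WT alone 1072 passed, of which 178 also passed the interaction, and 250 passed in W89A alone, of which 41 did. A call in a single strain is not by itself a difference between strains.

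**Figure D1:**
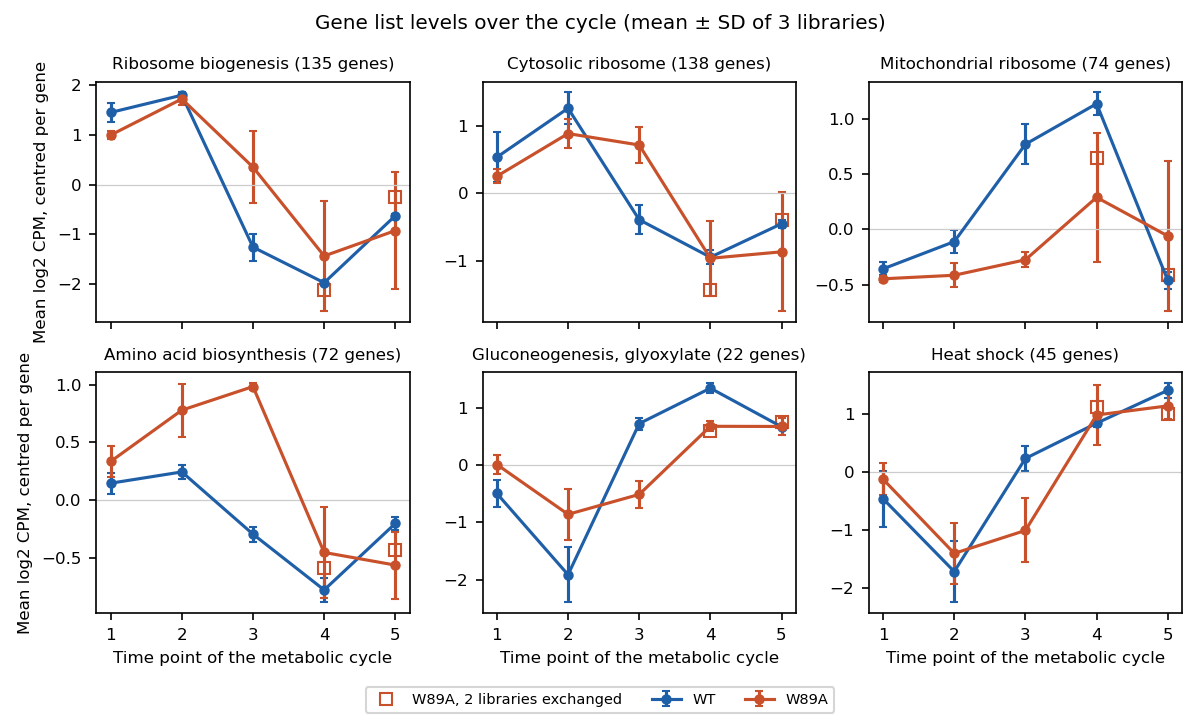
Mean log2 CPM of 6 gene lists, centred per gene, against the time point of the metabolic cycle in WT and W89A; points are means and bars the SD of 3 libraries, and open squares give W89A time points 4 and 5 with the 2 first-cycle libraries exchanged. At time point 3, ribosome biogenesis stood at 0.35 in W89A and at -1.26 in WT.

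W89A time points 1, 2, 4 and 5 correlated best across cycling genes with the WT time point of the same number (Pearson r = 0.827, 0.937, 0.92 and 0.814), and W89A time point 3 with WT time point 2 (r = 0.61, against 0.073 with WT time point 3). The W89A library of cycle 3 carried most of this contrast: at time point 3 it gave 0.844 with WT time point 2 and -0.237 with WT time point 3, against 0.311 and 0.298 in cycle 1 and 0.37 and 0.246 in cycle 2. Without cycle 3 the values were 0.418 and 0.238. Genes are not independent replicates, so no p is given. By rank correlation W89A time point 5 was also closer to another number, WT time point 4 (0.795 against 0.794), which left 3 of 5 matches. The same held without WT cycle 2 (0.809 against 0.808), W89A cycle 2 (0.85 against 0.756) or W89A cycle 3 (0.848 against 0.729). These values are for the title order. With the first-cycle libraries exchanged, W89A time point 5 gave 0.878 with WT time point 5 and 0.565 with WT time point 4, and with both left out 0.88 and 0.555. Along the path through the WT time points, the 3 W89A libraries of time point 3 lay at positions 2.59, 2.56 and 2.24, and the WT ones at 3.14, 2.88 and 3.23. Their distances from the path (root mean square over genes of log2 CPM) were 0.562, 0.563 and 0.468, against 0.333, 0.289 and 0.258 for WT. Those of the other W89A libraries ran from 0.299 to 0.56. The W89A libraries of time point 3 therefore lay off the path, and their positions are approximate. The WT library of time point 1 in cycle 1 lay at 1.58 and the other 2 at 5.87 and 5.88, between time points 5 and 1. The W89A libraries of time point 1 lay at 5.81, 5.72 and 5.72. Those of time point 2 lay at 1.64, 1.68 and 1.23, against 2, 2 and 1.47 in WT. Whether W89A was sampled earlier than WT at time points 1 and 2 was not tested. The first-cycle W89A library of time point 4 lay at 5.17 and that of time point 5 at 4.11, while the other cycles lay at 4.06 and 3.27 and at 5.16 and 5.13.

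**Figure D2:**
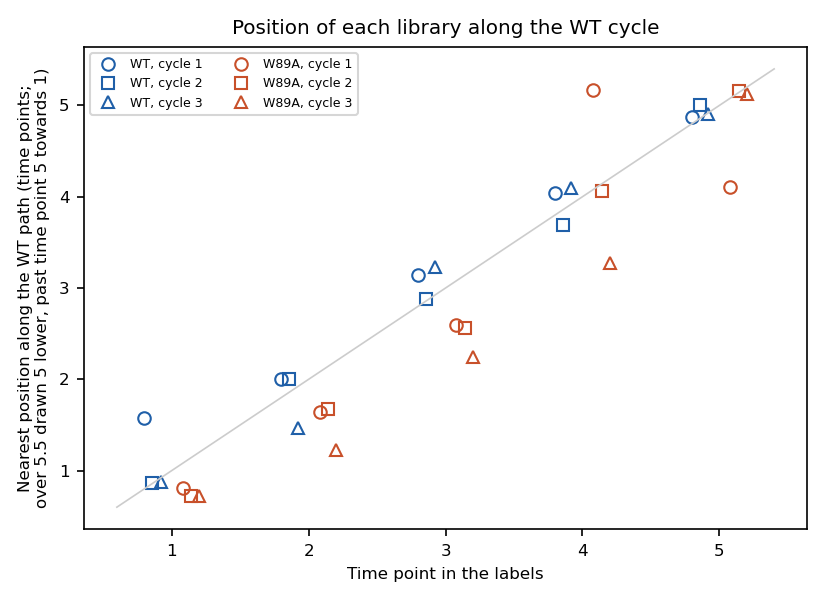
Nearest position of each library along the line joining the WT time points (vertical axis, in time points) against its time point by title order. Each WT library was placed on the path of the other WT libraries, and positions over 5.5 are drawn 5 lower. W89A libraries of time point 3 lay at 2.24 to 2.59, and the first-cycle W89A libraries of time points 4 and 5 lay at 5.17 and 4.11.

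Expression of YAF9 (YNL107W, chromosome XIV) did not pass the test at any time point, with an average log2 fold change of -0.08 ± 0.07 (SE; adjusted p = 0.325 in edgeR with Benjamini-Hochberg adjustment) from 25.91 CPM in WT and 24.05 in W89A. A transcript level does not check a point substitution. The histone variant gene HTZ1, whose product SWR1 inserts, did not pass either (-0.03 ± 0.07, adjusted p = 0.762). SWR1 itself (YDR334W), which encodes the catalytic subunit, was higher in W89A at all 5 time points, by 0.65 to 0.86, with an average of 0.71 ± 0.06 (adjusted p = 3.83e-08) and an interaction adjusted p of 0.867. Its call at time point 1 was lost without the WT library of cycle 1 or the W89A library of cycle 2 (highest adjusted p 0.0876), and its call at time point 5 without the WT or W89A library of cycle 1 (highest adjusted p 0.0672). Its average call held without any single cycle.

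Among the other subunits, averaged over the cycle, EAF1 was higher by 0.54 ± 0.07, EPL1 by 0.37 ± 0.09, VPS72, which binds Htz1, by 0.36 ± 0.05, BDF1 by 0.35 ± 0.10, TRA1 by 0.26 ± 0.05, SWC4 by 0.22 ± 0.06 and ESA1, the NuA4 acetyltransferase, by 0.16 ± 0.05. SWC5 (-0.33 ± 0.10) and EAF3 (-0.28 ± 0.05) were lower. ESA1 lost its call without WT cycle 1 or 3 (highest adjusted p 0.102), and SWC5 without WT cycle 3 or W89A cycle 2 (highest adjusted p 0.107). Of 15 SWR1 complex genes tested, 4 were higher and 1 lower, and of 13 NuA4 genes 5 were higher and 1 lower, the same counts when adjusted over the list alone. Neither list passed camera for the average (adjusted p = 0.209 and 0.207). At time point 4 both did, with medians of 0.20 and 0.30 (camera adjusted p = 0.017 and 0.0251; adjusted p = 0.678 and 0.636 with an estimated correlation). With the first-cycle libraries exchanged camera gave 0.0284 and 0.0347, and with both left out 0.039 and 0.0832, so NuA4 no longer passed.

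At time point 1, the genes furthest apart between the strains came from several pathways. Highest in W89A were COX26, a small cytochrome oxidase subunit (1.71 ± 0.39, from 15.37 ± 4.92 to 50.19 ± 16.65 CPM, SD, n = 3), the lactate dehydrogenase gene CYB2 (1.57 ± 0.33), the arginine biosynthesis gene ARG4 (1.56 ± 0.35), TMT1 (1.55 ± 0.29) and ADH5 (1.55 ± 0.32). Lowest were HXT4 (-1.71 ± 0.31), the allantoin genes DAL2 (-1.52 ± 0.41) and DAL1 (-1.28 ± 0.31), LOH1 (-1.28 ± 0.28) and the iron-sulfur scaffold gene ISU2 (-1.24 ± 0.16). Amino acid biosynthesis genes were higher in 5 of 72 (median 0.13), or 12 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0182, or 0.916 with an estimated correlation). Adjusted over all genes, 10 were higher and 3 lower with the first-cycle libraries exchanged, and 12 and 3 with both left out. The nitrogen catabolite list, which holds DAL1 and DAL2, did not pass camera (adjusted p = 0.0968). Trehalose and glycogen genes had a median of 0.80, with 3 of 21 higher, among them NTH2 (0.62) and GLG1 (0.82), and 7 exchanged and 6 left out. Adjusted over the list alone, 13 were higher by title order (camera adjusted p = 2.05e-08, or 0.697 with an estimated correlation). Respiratory chain genes had a median of 0.26, with 1 of 39 higher, QCR10 (0.62), and 5 exchanged and 6 left out. Adjusted over the list alone, 5 were higher by title order (camera adjusted p = 4.48e-07, or 0.761 with an estimated correlation). Opposite to time point 3, ribosome biogenesis genes had a median of -0.45, with 0 of 135 past the threshold, also when adjusted over the list alone, and 5 lower exchanged or left out (camera adjusted p = 1.59e-08; adjusted p = 0.866 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.28, with 1 of 138 lower, 0 when adjusted over the list alone and 2 exchanged (camera adjusted p = 0.000134; adjusted p = 0.928 with an estimated correlation). The W89A libraries of this time point lay at positions 5.81, 5.72 and 5.72. Whether they were sampled earlier than WT was not tested. The WT library of cycle 1 lay apart from the other 2 of this time point, at position 1.58 against 5.87 and 5.88. Without it the median was 0.47 for trehalose and glycogen, 0.31 for the respiratory chain, -0.33 for ribosome biogenesis and 0.21 for amino acid biosynthesis, and these 4 lists still passed camera at the preset correlation. That of the cytosolic ribosome was -0.08 and no longer passed (camera adjusted p = 0.33). The amino acid list no longer passed without the W89A library of cycle 1 or the WT library of cycle 2 or 3 (camera adjusted p = 0.312, 0.135 and 0.0827).

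The threshold was passed at time point 1 by 178 of 6256 genes, 99 higher and 79 lower, and by 37 with at least a 2-fold change. The balance depends on the scaling: DESeq2 size factors gave 80 higher and 92 lower, and leaving out the 10 most abundant genes and the mitochondrial genome gave 76 and 79. With the first-cycle W89A libraries of the later time points exchanged or left out, which here changes the estimate of spread and, slightly, the scaling, the count was 501 or 478, and DESeq2 called 424. It was 11 without the WT library of cycle 1 and 22 without that of cycle 3. It was 42, 11 and 72 without the W89A library of cycle 1, 2 and 3. Of the 10 genes named first, ISU2 kept its call in every such fit and DAL2 in none. NTH2, GLG1 and QCR10 lost theirs in all 6 as well (highest adjusted p 0.216, 0.246 and 0.167).

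At time point 2, some genes of amino acid synthesis and of gluconeogenesis and the glyoxylate cycle were higher in W89A. The highest were ARO5 (YGL117W; 2.88 ± 0.44), ADY2 (2.69 ± 0.57), TMT1 (2.58 ± 0.30), the sulfite exporter gene SSU1 (2.51 ± 0.43) and the autophagy gene ATG41 (2.47 ± 0.22, from 58.52 ± 8.69 to 323.7 ± 103 CPM, SD, n = 3). The lowest were GAS2 (-1.81 ± 0.36), the polyamine exporter gene TPO2 (-1.56 ± 0.21), HXT4 (-1.50 ± 0.30), ATG10 (-1.20 ± 0.32) and MPF1 (-1.10 ± 0.27). Amino acid biosynthesis genes were higher in 19 of 72 and lower in 0, among them TRP4 (1.55) and LEU4 (1.46), or 30 higher and 2 lower when adjusted over the list alone (median 0.41, camera adjusted p = 8.82e-08; adjusted p = 0.761 with an estimated correlation). Genes of the gluconeogenesis and glyoxylate list were higher in 10 of 22, or 12 when adjusted over the list alone (median 0.93, camera adjusted p = 2.23e-09, or 0.526 with an estimated correlation). This list also holds carnitine genes, among them the 2 named by rule, YAT2 (1.61) and CRC1 (1.89). Cytosolic ribosomal protein genes had a median of -0.36, with 1 of 138 lower, 0 when adjusted over the list alone and 3 exchanged or left out (camera adjusted p = 6.1e-06; adjusted p = 0.916 with an estimated correlation). The mitochondrial ribosome had a median of -0.30, with IMG1 lower (-0.89). The 1 listed gene that was higher, YMR1 (0.51), is a lipid phosphatase gene that the list's name pattern took in, as it took RPP1, an RNase P gene, into the cytosolic ribosome list. Of these 74 genes, 0 passed by title order when adjusted over the list alone (camera adjusted p = 2.34e-06, or 0.866 with an estimated correlation). Adjusted over all genes, 24 were lower with the first-cycle libraries exchanged and 23 with both left out.

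At time point 2, 486 genes passed, 349 higher and 137 lower, 123 of them 2-fold or more. The count was 818 with the first-cycle libraries exchanged and 786 without them. It was 157 and 255 without the WT library of cycle 1 and 2, and 168 and 268 without the W89A library of cycle 1 and 2. Of the 10 genes named first, 8 kept their call in each fit without 1 library; ATG10 lost it without the WT library of cycle 1 or 2 or the W89A library of cycle 1 (highest adjusted p 0.126), and MPF1 without the W89A library of cycle 1 or 2 (highest adjusted p 0.0863). IMG1 lost its call without the WT library of cycle 1 or the W89A library of cycle 1 or 2 (highest adjusted p 0.127), and YMR1 in all such fits except that without the WT library of cycle 3 (highest adjusted p 0.123).

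Time point 3 had more genes past the threshold than any other time point. Transcripts for building ribosomes and for amino acid synthesis were higher in W89A, and those for the mitochondrial ribosome, gluconeogenesis and the glyoxylate cycle, and stress were lower. The highest were SRL4 (3.52 ± 0.49), HXT4 (3.35 ± 0.33, from 14.03 ± 2.85 to 143.4 ± 22.02 CPM, SD, n = 3), DBP2 (3.01 ± 0.64), the CTP synthase gene URA7 (2.81 ± 0.69) and the pyrimidine nucleotidase gene SDT1 (2.73 ± 0.26). The lowest were SIP18 (-3.71 ± 0.93), the nitrogen catabolite repressor gene DAL80 (-3.46 ± 0.60), ACS1 (-3.05 ± 0.56, from 1677 ± 260.3 to 202.7 ± 39.09 CPM), the carnitine acetyltransferase gene CAT2 (-2.94 ± 0.52) and the chaperone gene HSP26 (-2.93 ± 0.69). All 10 kept their call in each fit without 1 library.

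Ribosome biogenesis genes were higher in 131 of 135 (median 1.66), among them TIF6 (1.22 ± 0.19) and UTP20 (2.05 ± 0.38). Cytosolic ribosomal protein genes were higher in 123 of 138 (median 1.10), among them RPS0B (1.66 ± 0.30) and RPS8B (1.60 ± 0.30). RNA polymerase I and III genes were higher in 19 of 20 (median 1.16), and translation factor and tRNA synthetase genes in 40 of 46, with DPS1 (1.27) and TYS1 (1.11). Amino acid biosynthesis genes were higher in 52 of 72 (median 1.18), led by ARO3 (2.53 ± 0.22) and TRP4 (2.25 ± 0.20). Of its 3 lower members, GDH3 (-2.29 ± 0.29) and the aminotransferase gene BAT2 (-1.15 ± 0.16) had the smallest p. Mitochondrial ribosomal protein genes were lower in 72 of 74 (median -1.06), with MRPL28 (-1.26 ± 0.21) and IMG1 (-1.46 ± 0.24). Genes of the gluconeogenesis and glyoxylate list were lower in 18 of 22 (median -1.72), with the carnitine acetyltransferase gene YAT1 (-2.22 ± 0.27) and IDP2 (-1.74 ± 0.24). Heat shock genes were lower in 30 of 45 (median -1.33), with GCY1 (-2.22 ± 0.32), while the stress regulator gene MSN4 was higher (0.70 ± 0.15). Adjusted over the list alone, the counts were 134, 126, 19, 41 and 52 higher, and 72, 20 and 30 lower. Camera adjusted p ran from 1.01e-19 for the mitochondrial ribosome to 6.07e-06 for the polymerases, and adjusted p = 0.526 to 0.782 with an estimated correlation.

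In all, 2942 genes passed at time point 3, 1624 higher (55.2%) and 1318 lower, and 1120 changed 2-fold or more. Leaving out the 10 most abundant genes and the mitochondrial genome before scaling moved the median of all genes by -0.128 on the log2 scale and gave 42.9% higher among 2949 calls, so the balance of higher against lower depends on the scaling.

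At time point 4, many genes of the G2 and M phases and of daughter cell separation were higher in W89A, and many of the mitochondrial ribosome and histones were lower. The highest were the chitinase gene CTS1 (1.53 ± 0.35, 1.003 with the first-cycle libraries exchanged), the daughter-specific glucanase gene DSE2 (1.43 ± 0.39, 0.77 exchanged), the mitotic cyclin gene CLB2 (1.34 ± 0.19, 1.16 exchanged), BAS1 (1.34 ± 0.36, 0.71 exchanged) and ASG1 (1.32 ± 0.28, 0.88 exchanged). The lowest were the near-identical thiamine genes THI12 (-1.81 ± 0.46), THI5 (-1.74 ± 0.50) and THI13 (-1.58 ± 0.37), the pyruvate decarboxylase gene PDC6 (-1.53 ± 0.44) and the malate synthase gene MLS1 (-1.51 ± 0.43), which were at -1.90, -1.75, -1.45, -1.71 and -1.76 exchanged. All 10 passed in both assignments. Without both libraries, DSE2 (0.56, adjusted p = 0.142) and MLS1 (-1.35, adjusted p = 0.0576) did not. CLB2, ASG1 and THI13 alone of the 10 kept their call in each fit without 1 library. CTS1, DSE2, BAS1, THI12, THI5 and MLS1 lost theirs without the W89A library of cycle 1 (adjusted p = 0.0903, 0.272, 0.121, 0.058, 0.0604 and 0.0885). DSE2, BAS1, THI5 and PDC6 lost theirs without the WT library of cycle 3, MLS1 without that of cycle 2, and PDC6 without the W89A library of cycle 3 (highest adjusted p 0.0579).

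Mitochondrial ribosomal protein genes were lower in 45 of 74 at time point 4 (median -0.85), with IMG1 (-1.46 ± 0.24) and RSM19 (-1.33 ± 0.22). Exchanged, 52 were lower with a median of -0.49, and with both libraries left out 41. Adjusted over the list alone, 64 were lower by title order. Histone genes were lower in 8 of 11 (median -0.78), 8 exchanged and 7 left out, with HTB1 (-0.82 ± 0.18) and the linker histone gene HHO1 (-0.72 ± 0.13). Over the list alone, 9 histone genes were lower by title order. Genes of the G2 and M phases were higher in 18 of 35 (median 0.43), 16 exchanged and 12 left out, with CLB2 and IQG1 (0.71 ± 0.10). Over the list alone, 21 of them were higher by title order. Daughter separation genes were higher in 11 of 15 (median 0.92) and in 9 exchanged, but in 1 with both libraries left out. Over the list alone, 14 of them were higher by title order. The level of this list in W89A, as log2 CPM centred per gene, was 0.161 by title order and -0.089 exchanged, against -0.741 in WT. Camera adjusted p were 3.15e-24, 5.75e-06, 4.91e-08 and 3.11e-05 in this order, and adjusted p = 0.696, 0.526, 0.195 and 0.76 with an estimated correlation. Ribosome biogenesis had a median of 0.52, with 11 of 135 higher, and of -0.11 exchanged, with 0 higher and 2 lower; 0 passed when adjusted over the list alone (camera adjusted p = 0.00353; adjusted p = 0.937 with an estimated correlation).

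Of 1224 genes past the threshold at time point 4, 741 (60.5%) were higher, against 46% of the calls with the 10 most abundant genes and the mitochondrial genome left out before scaling; 167 changed 2-fold or more. Exchanging the libraries gave 1334 calls, 944 of them shared, and leaving both out 842. The count was 780 and 508 without the WT library of cycle 1 and 3, and 521 without the W89A library of cycle 1. A fit of the 6 libraries of this time point alone called 0 genes by title order in edgeR (1395 at an unadjusted p under 0.05) and 487 exchanged, where DESeq2 called 1144. DESeq2 over all 30 libraries called 1469 by title order.

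Time point 5 rested on the same uncertain libraries. The highest were the transcription factor gene TEC1 (1.64 ± 0.44), the isocitrate dehydrogenase genes IDH2 (1.51 ± 0.45) and IDH1 (1.42 ± 0.36), the pheromone gene MF(ALPHA)1 (1.30 ± 0.31) and the glutamine permease gene GNP1 (1.19 ± 0.27). Exchanged, these were at 0.61, 0.63, 0.77, 0.78 and 1.19, and TEC1 (adjusted p = 0.0547) and IDH2 (adjusted p = 0.0712) no longer passed. The lowest were THI12 (-1.88 ± 0.47), THI5 (-1.67 ± 0.50), the arginine synthesis gene ARG1 (-1.48 ± 0.43), the cyclin gene PCL5 (-1.39 ± 0.30) and THI13 (-1.38 ± 0.37), at -1.79, -1.66, -1.26, -1.23 and -1.52 exchanged, where ARG1 no longer passed (adjusted p = 0.0642). Without both libraries, IDH1 alone of these 10 passed (0.68, adjusted p = 0.0421). Amino acid biosynthesis genes, opposite to time point 3, had a median of -0.30 (-0.19 exchanged), with 3 of 72 lower, 5 lower and 2 higher exchanged and 0 left out. Adjusted over the list alone, 5 were lower and 1 higher by title order (camera adjusted p = 0.000177, or 0.782 with an estimated correlation). Proteasome genes were lower in 4 of 37 (median -0.20; -0.12 and 4 exchanged; 2 with both libraries left out), with RPN10 (-0.68 ± 0.11) and PUP3 (-0.53 ± 0.11), and in 13 when adjusted over the list alone (camera adjusted p = 8.32e-06; adjusted p = 0.782 with an estimated correlation). Mitochondrial ribosome genes had a median of 0.41 with 6 of 74 higher, among them MRPL22 (0.69) and MRPS17 (0.85), 14 when adjusted over the list alone, and of 0.04 exchanged, with 5 higher and 1 lower, and left out 0 were higher and 1 lower (camera adjusted p = 1.04e-09, 0.394 exchanged and 0.754 left out; adjusted p = 0.782 with an estimated correlation).

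At time point 5, 362 genes passed, 171 higher (47.2%, against 51.5% by DESeq2 size factors and 59.1% with the most abundant genes left out before scaling) and 191 lower, 46 of them 2-fold or more. The count was 595 with the libraries exchanged, 295 shared, 116 with both left out, and 641 by DESeq2. It was 50, 161 and 69 without the WT library of cycle 1, 2 and 3, 22 without the W89A library of cycle 1 and 628 without that of cycle 3. Of the 10 genes named above, 0 kept their call in every such fit. All 10 lost it without the W89A library of cycle 1, as did PUP3 (adjusted p = 0.0646), MRPL22 and MRPS17, while RPN10 kept it throughout. A fit of the 6 libraries alone called 0 genes by title order in edgeR (893 at an unadjusted p under 0.05) and 1086 exchanged, where DESeq2 called 1326.

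**Figure D3:**
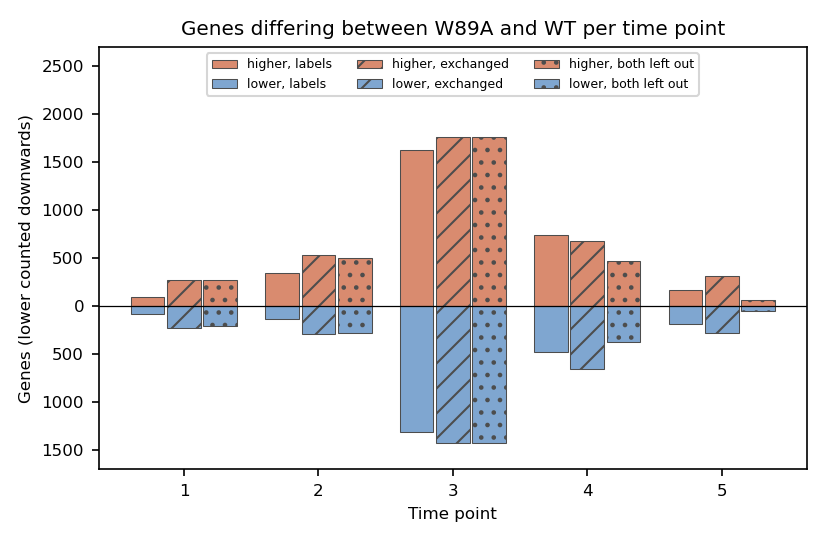
Number of genes higher (upward) and lower (downward) in W89A than in WT at each time point, by edgeR with Benjamini-Hochberg adjustment, for the title order, for the 2 first-cycle libraries exchanged and for both left out. Time point 3 had 1624 genes higher and 1318 lower by title order.

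Averaged over the cycle, most genes of amino acid synthesis, daughter cell separation and Ty elements were higher in W89A, and most of the mitochondrial ribosome were lower. Highest were the vitamin B6 gene SNO1 (1.29 ± 0.14), the alpha-agglutinin gene SAG1 (1.02 ± 0.33), the iron oxidase gene FET3 (1.02 ± 0.13), the sodium pump gene ENA1 (0.97 ± 0.16), UTR2 (0.96 ± 0.14), DSE2 (0.89 ± 0.17), CTS1 (0.88 ± 0.15), GGC1 (0.86 ± 0.13), the aromatic aminotransferase gene ARO8 (0.85 ± 0.12) and GLN3, an activator of nitrogen catabolite genes (0.83 ± 0.08). Lowest were THI12 (-1.66 ± 0.21), OYE3 (-1.23 ± 0.22), the GABA permease gene UGA4 (-1.15 ± 0.20), DAL2 (-1.05 ± 0.18), THI11 (-1.03 ± 0.16), SIP18 (-1.02 ± 0.36), DAL1 (-1.003 ± 0.14), IMG1 (-0.97 ± 0.11), the glutamate dehydrogenase gene GDH3 (-0.93 ± 0.12) and the spore wall gene DIT1 (-0.92 ± 0.09). All had the same sign at all 5 time points, and 18 of the 20 kept their call without any single cycle; SAG1 lost it without WT cycle 2 or 3 (highest adjusted p 0.122) and SIP18 without WT cycle 3 or W89A cycle 2 (highest adjusted p 0.258).

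Mitochondrial ribosomal protein genes were lower in 46 of 74 on average (median -0.38), 70 exchanged and 69 with both first-cycle libraries left out. Adjusted over the list alone, 56 were lower by title order. Among the lower genes was RSM19 (-0.72 ± 0.10) beside IMG1, and YMR1 was the listed gene that was higher (0.34 ± 0.07). Amino acid biosynthesis genes were higher in 47 of 72 and lower in 2 (median 0.37), 47 and 3 when adjusted over the list alone, with ARO3 (1.04 ± 0.09) and TRP4 (0.88 ± 0.09) against GDH3 and BAT2 (-0.53 ± 0.07). Daughter separation genes were higher in 11 of 15 (median 0.49), the same count when adjusted over the list alone, with PIR1 (0.64 ± 0.12). Ty element genes, whose copies share reads, were higher in 25 of 44 (median 0.44), 26 when adjusted over the list alone. Histone genes were lower in 7 of 11 (median -0.26), the same count when adjusted over the list alone, with HHO1 (-0.36 ± 0.06) and HTB1 (-0.32 ± 0.08). Camera adjusted p were 3.33e-13, 1.3e-07, 0.00109, 2.37e-05 and 0.017 in this order, and adjusted p = 0.782, 0.761, 0.782, 0.526 and 0.782 with an estimated correlation. In all, 2661 genes passed, 1509 higher (56.7%) and 1152 lower, and 95 of them changed 2-fold or more. With the 10 most abundant genes and the mitochondrial genome left out before scaling, 1217 were higher (46.9%) and 1376 lower. The nitrogen catabolite list had a median of -0.13, with 5 of 28 higher and 8 lower, the same counts when adjusted over the list alone, and did not pass camera (adjusted p = 0.157).

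The strain difference itself changed between time points for 2010 genes (edgeR interaction, Benjamini-Hochberg). This test cannot tell a changing strain effect from sampling W89A at another point of the cycle, which its positions at time point 3 leave possible. HXT4 was lower in W89A at time points 1 and 2 (-1.71 and -1.50) and higher at time point 3 (3.35). The aromatic and sulfur amino acid genes ARO3, TRP4 and STR2 were higher most at time point 3 (2.53, 2.25 and 1.75), with values of -0.49, -0.58 and -0.32 at time point 5 that did not pass. RIB5 and SDT1 were higher at time point 3 (1.98 and 2.73) and lower at time point 5 (-0.83 and -0.83). At time point 5, RIB5 was at -0.83 exchanged and -0.71 with both libraries left out (adjusted p = 0.0061 and 0.0506), and SDT1 at -0.78 and -0.73 (adjusted p = 0.0503 and 0.149), so the call of SDT1 held by title order alone. ATG41 was higher at time point 2 (2.47) and lower at time point 5 (-1.18, -1.17 exchanged, adjusted p = 0.0303 left out). STL1 and the carnitine acetyltransferase gene YAT1 were lower at time point 3 (-2.90 and -2.22), while STL1 was higher at time point 1 (0.95) and YAT1 at time point 2 (1.21). The citrate carrier gene CTP1 was lower at time point 1 (-0.78) and higher at time point 3 (1.55). The calls of STL1 and CTP1 at time point 1 lay near the threshold (edgeR adjusted p = 0.0427 and 0.0334), where the count of calls fell to as few as 11 without 1 library. All 10 genes kept their interaction call with any single cycle left out. The interaction count was 449, 773 and 747 without WT cycle 1, 2 and 3, and 1121 without W89A cycle 3.

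By list, the interaction passed for 68 of 74 mitochondrial ribosome genes, 98 of 138 cytosolic ribosome genes, 89 of 135 ribosome biogenesis genes and 55 of 72 amino acid biosynthesis genes, and for 1 of 37 proteasome genes. With the first-cycle libraries exchanged it passed for 69, 129, 134, 58 and 6 of them, and for 2620 genes in all, 1957 of which also passed by title order.

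The median range of cycling genes over a cycle was 1.19 ± 0.06 on the log2 scale in WT and 1.07 ± 0.09 in W89A (SD, n = 3 cycles), a difference of -0.12 that did not pass an exact permutation test (2-sided p = 0.2, where 0.1 is the smallest p that 3 against 3 allows). The range of gluconeogenesis and glyoxylate genes was 3.57 ± 0.56 in WT and 2.12 ± 0.12 in W89A. That of the mitochondrial ribosome was 1.69 ± 0.05 and 1.20 ± 0.15, that of histones 1.04 ± 0.28 and 0.55 ± 0.07, and that of amino acid biosynthesis genes 1.45 ± 0.06 and 1.998 ± 0.36 (n = 3 cycles each). The SWR1 complex list had 0.80 ± 0.07 in WT and 0.55 ± 0.08 in W89A, and the NuA4 list 0.74 ± 0.03 and 0.52 ± 0.04. For these lists, and for some others not described here, all cycles of one strain lay beyond those of the other (exact permutation p = 0.1, Benjamini-Hochberg adjusted p = 0.315 over all lists), which does not reach the threshold.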

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

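For the difference at time point 3, the test of its direction was chosen after the result was seen, as were both tests of the exchanged libraries and, for the mitochondrial ribosome, the comparison of each member with its own matched genes and the condition on intervals.

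The strain difference changed between time points for 2010 genes by the interaction test, which is why they are given here. The interaction cannot tell a strain effect that changes over the cycle from W89A sampled at another point of the cycle. The 10 named genes had adjusted p (edgeR, Benjamini-Hochberg) of 6.43e-07 for ATG41, 8.6e-07 for HXT4, 8.7e-07 for STL1, 1.48e-06 for RIB5, 1.75e-06 for SDT1, 2.57e-06 for TRP4, 2.68e-06 for STR2, 8.39e-06 for ARO3, 1.26e-05 for CTP1 and 1.39e-05 for YAT1. Of 344 other genes named by rule, 191 passed as well.

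For each comparison of 3 libraries with 3, or of 3 cycles with 3, the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 178 and 1 at time point 1, 486 and 0 at time point 2, 2942 and 0 at time point 3, 1224 and 35 at time point 4, 362 and 1 at time point 5, 2661 and 5 for the average and 2010 and 0 for the interaction. For the change over the cycle, 1 of 100 splits, the real one, gave as many genes: 4977 against at most 3369 in WT and 4155 against at most 3334 in W89A. This argues against chance there, though 100 splits allow no share under 1 in 100.

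The first pattern is the difference at time point 3, where 2942 genes passed. Leaving out the 10 most abundant genes and the mitochondrial genome before scaling called 2949 genes, 2579 of them shared with the 2942. This argues against a few abundant genes taking a changed share of the reads as the cause of most calls. The same change moved the median of all genes by -0.128 on the log2 scale and gave 1264 higher and 1685 lower, so the balance did depend on them. Sampling W89A at an earlier point of the cycle may account for part of it: the difference correlated with WT time point 2 minus time point 3 at r = 0.753, and 1650 of the 2942 genes (56.1%) lay between those WT means, with 131 of 131 called ribosome biogenesis genes but 16 of 72 of the mitochondrial ribosome, 5 of 55 of amino acid biosynthesis and 3 of 20 of the proteasome. For the 14.8% of genes whose W89A libraries lay beyond all 15 WT libraries, among them 44 higher and 1 lower of 55 called amino acid biosynthesis genes, earlier sampling and an effect of the substitution cannot be told apart, since 5 time points leave gaps in the WT cycle. The culture and an effect of W89A on the timing of the cycle stay open and were not tested.

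The second pattern is that the first-cycle W89A libraries of time points 4 and 5 lay apart from the others. A first cycle that ran ahead or behind is argued against, because 1 was displaced by 1.5 time points and the other by -1.03, in opposite directions. A candidate explanation is that the 2 libraries carry each other's time point: 2 of 2 correlated better with the other W89A libraries of the exchanged time point than with those of their own (r = 0.851 against 0.504 and 0.917 against 0.58), and the authors' tables list them that way. Of the other 13 W89A libraries, 3 also correlated better with another time point, but for 1 of them, time point 4 of cycle 2, the compared groups held the 2 libraries in question, and against WT it was closest to its own time point (0.921, against 0.53 with time point 5). Against WT, the first-cycle library of time point 4 gave 0.795 with time point 5 and 0.555 with time point 4. That of time point 5 gave 0.896 with time point 4 and 0.552 with time point 5. With the exchange, the common coefficient of variation fell from 0.1995 to 0.1639. The edgeR fits of 6 libraries called 487 and 1086 genes at time points 4 and 5, against 0 at each by title order. These values and the authors' tables argue against the title order for these 2 libraries, though no further source was used to settle it.

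The final pattern is the lower mitochondrial ribosome genes in W89A averaged over the cycle, with a median log2 fold change of -0.345 in the edgeR fit (95% interval -0.378 to -0.301). The intervals here come from resampling genes, which move together, so they do not measure the spread between cycles. Gene length or expression level are argued against, since 0 of 10000 random lists matched for both were as low (lowest -0.228). Genes of the nearest WT profile had a smaller decrease, with a median of -0.157 (-0.243 to -0.076). Since the intervals leave out the spread between cycles, they cannot decide whether sampling at other points of the cycle was the whole cause. Against its own matches, however, each member's median difference was -0.075 (-0.146 to -0.003), with 45 of 74 members below, so the matched genes (-0.267 per member) shared most of the decrease and sampling may account for that share. An effect of the substitution on the rest is a hypothesis that was not tested, since no separate cultures were stated.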

How the results depend on the processing

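Alternatives that exchange or leave out the first-cycle W89A libraries of time points 4 and 5, alone or with another choice, a block by strain, and list tests without each library of time point 1 were chosen after seeing the data. Where no cause is given, the cause was not tested.

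An added 2-fold minimum gave 37, 123, 1120, 167 and 46 genes at time points 1 to 5, 95 for the average, and 2920 and 2214 for the cycle in WT and W89A, by construction fewer. The exchange gave 501, 818 and 595 at time points 1, 2 and 5, and leaving both out 478, 786 and 116. The common coefficient of variation was 0.1639 and 0.1636 in these fits, against 0.1995. The exchange with a replicate block gave 548, 867 and 674, and the exchange without W89A cycle 3 gave 882, 936 and 1029. DESeq2 gave 424 and 641 at time points 1 and 5. Fits of 6 libraries gave 837 at time point 1, in both assignments, 0 at time points 4 and 5 in edgeR (1395 and 893 at an unadjusted p under 0.05), and 487 and 1086 there exchanged. DESeq2 over 6 exchanged libraries gave 1096, 962 and 1326 at time points 1, 2 and 5. The list calls fell from 104 to 0 with an estimated correlation, and the matches of time points from 4 to 3 by rank correlation.

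A replicate block gave 212, 478, 2917, 1227 and 384 genes at time points 1 to 5, 2629 for the average and 1879 for the interaction, and no filter on low counts 149, 454, 2897, 1173, 309, 2609 and 1940, all within 1.5 times.

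Without 1 library or cycle, counts ranged from 11 to 146, 157 to 521, 2151 to 2727, 508 to 1648 and 22 to 628 at time points 1 to 5. They ranged from 1789 to 2480 for the average, 449 to 2203 for the interaction, 4285 to 5008 for the cycle in WT and 3237 to 4156 in W89A. Of 96 list results at time point 1 without 1 library, 85 still passed and 11 did not, all in the same direction. The amplitude difference ranged from -0.158 to -0.07 and the matches from 3 to 4. Fewer libraries lower the power of each test.

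Lists whose direction relative to other genes reversed with the exchange were, by their medians, ribosome biogenesis at time point 4 (-0.106) and, at time point 5, cytosolic ribosome (0.045), ribosome biogenesis (0.368) and mitochondrial import (0.02, the sign of its 0.187 by title order); with both left out they were, at time point 5, 0.096, 0.371 and -0.022. Of 590 results on named genes, 588 kept direction and side of the threshold under DESeq2, 575 under its size factors, 578 with the block, 570 exchanged and 517 with both left out. With the 10 most abundant genes and the mitochondrial genome left out, 555 of 588 did. Genes that reversed had not passed: YAF9 at time point 3 (-0.038) and ARP6 on average (-0.013) with abundant genes left out, and YAF9 at time point 5 (0.0013) with both libraries left out. Without 1 library or cycle, 2778 of 3540 results on named genes kept direction and side of the threshold, 747 lost their call and 14 reversed. Values without 1 library ranged from -0.0225 to 0.179 and -0.281 to 0.0013 for YAF9 at time points 3 and 5. They ranged from -0.0731 to 0.185, -0.176 to 0.0111 and -0.0976 to 0.078 for HTZ1 at time points 2 and 3 and on average. On average they ranged from -0.00082 to 0.0771 for ARP4, -0.0023 to 0.0774 for ARP6, -0.355 to 0.729 for SWC7 and -0.0358 to 0.0225 for EAF6. In simulated counts of this depth, 41.8% of 1.5-fold changes at 1 time point were found among genes with a mean of at least 10 CPM.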

Other observations

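Further list results at single time points and on average were as follows. Ty element genes had medians of 0.50 and 0.51 at time points 2 and 5, with 8 and 7 of 44 higher, 11 and 10 when adjusted over the list alone, and with 1 of 44 higher at time point 5 when both first-cycle libraries were left out (camera adjusted p = 1.24e-05 and 1.53e-07; adjusted p = 0.526 and 0.501 with an estimated correlation). PAU genes, which share reads between copies, had a median of -0.48 on average, with 10 of 18 lower and 1 higher, the same counts when adjusted over the list alone (camera adjusted p = 0.00468; adjusted p = 0.429 with an estimated correlation). Cell wall genes had a median of 0.56 at time point 3, with 22 of 36 higher and 2 lower, the same counts when adjusted over the list alone (camera adjusted p = 0.000644; adjusted p = 0.708 with an estimated correlation). Genes within 30 kb of a chromosome end had a median of -0.11 at time point 4, with 29 of 354 higher and 44 lower, 30 and 45 when adjusted over the list alone (camera adjusted p = 0.0243, and 0.2 with the first-cycle libraries exchanged and 0.156 with both left out; adjusted p = 0.195 with an estimated correlation).

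Among genes that passed at time point 3, 9 had the 3 W89A libraries of each of the 5 time points beyond all 15 WT libraries: OST1, SNQ2, WHI3, NUP116, CUE1, GEM1, MDM12, HNT3 and GEX2. They were chosen after their values were seen. The 20 genes nearest SWR1 on its chromosome had a median average difference of 0.051 (-0.48 to 0.763), and 10 of the 20 passed.

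The authors' tables list 1088, 952, 2994, 1117 and 1244 genes with an adjusted p under 0.05 at time points 1 to 5. DESeq2 over the 6 libraries of each time point, with the first-cycle libraries exchanged as in those tables, gave 1096, 962, 3014, 1144 and 1326.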
